A study of Danio rerio with 48 samples.

How the data were processed

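Transcripts of wild type zebrafish were measured by bulk RNA sequencing in whole embryos and in yolk tissue at 6, 10, 26 and 48 hpf. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra II RNA kit. The labels list 48 samples, and 16 of body tissue were not analysed here. The remaining 32 libraries, 4 per tissue and age, were assigned to groups and replicate numbers from the sample titles.

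The deposited values were raw counts per gene symbol, 1 column per library, with no normalization and no pooling of replicates. FastQC 0.12.1, Trim Galore 0.6.10, STAR 2.7.10b, featureCounts 2.0.6 and the genome build GRCz11 are named per the submitters' processing notes. Their settings, the annotation and the strand setting are not given in the sources used here. Antisense and overlapping genes could therefore not be told apart, and reads of near-identical copies may be split or lost. Genes appear by symbol only, without coordinates, because no annotation of that build was used here.

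Library totals ran from 32302472 to 39765045 counts. The table held 36109 genes, of which 2752 had 0 counts in every library, and 26268 were kept by filterByExpr with a minimum count of 10 and a minimum total of 15. No pair of replicates agreed within sampling noise, as a library entered 2 times would (chi-square per gene at least 17.6), so none were merged. This does not show that they were independent.

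Counts were scaled by TMM and fitted with the robust quasi-likelihood model of edgeR 4.0.16 in R 4.3.3. A single fit held 8 group means, which left 24 residual degrees of freedom. The common dispersion was 0.172. The 12 contrasts were yolk against whole embryo at each of 4 ages, the 3 steps between ages in each tissue, and 2 differences of changes between tissues. Tests were two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05 on the adjusted p. Standard errors are the log2 change over the root of its F statistic.

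Before the data were examined, 27 gene lists were fixed, and mitochondrially encoded and cytosolic ribosomal protein genes brought them to 29. Each list was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and adjustment over the 29 lists of a contrast. Every camera test was repeated with an estimated correlation, which kept 27 of 175 calls. Members were matched by symbol, 5 of them through a synonym in a RefSeq gene table. No match was found for 8 symbols, among them apoa4b.3, apoh and slc7a1a. Results of some single list members are not reported here. Some genes belong to more than 1 list, as with gata5 and gata6 of the syncytial layer and transcription factor lists. The text on each comparison describes a selection of lists, and at 48 hpf all lists are given for yolk against whole embryo.

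Named genes followed a rule fixed at the same time. It took the focal genes, the 5 largest changes per direction in the 7 contrasts within or against yolk, and 3 in the others. These had to pass the test, reach a mean of 10 CPM in the higher group and bear a gene symbol that is not a clone name. In contrasts of 2 groups the libraries also had to be fully separated. From each list up to 4 members with the largest change and 2 with the highest level were eligible. A gene with 0 counts in a group has a lower bound of its fold against 3 counts over that group. With 1 to 3 counts the ratio has an exact 95% counting interval. Such bounds and intervals cover counting error only. List medians are also given with 0-count genes at their bound where that moved the median.

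Same-numbered libraries deviated together from their group means in some contrasts, over 9034 genes above a log2 CPM of 3. For yolk against whole embryo the correlations were 0.23 to 0.43 at 6 hpf, 0.19 to 0.38 at 10 hpf, 0.22 to 0.31 at 26 hpf and 0.2 to 0.41 at 48 hpf. Yolk at 10 against 6 hpf gave 0.22 to 0.3, and differently numbered libraries reached at most 0.12 in these 5 contrasts. Every pair there lay above the limit of 0.1, so the numbers pair the libraries. The pairing comes from the data, and the labels do not say what a number marks. The other steps had at least 1 pair under that limit. A replicate block was fitted as an alternative on all libraries. Blocked list counts come from a replicate block on the libraries of the contrast alone, and are given where they moved by more than 1 gene and by over 1.5 times.

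Other alternatives were size factors of DESeq2 1.42.0, library totals alone, no low-count filter, the DESeq2 Wald test, a fit of the libraries of the contrast alone, removal of mitochondrially encoded genes and removal of each library in turn. Added after the data were seen were removal of COX3 with those genes, the block with the contrast's libraries alone, lists without yolk replicate 1 of 26 hpf and lists under other scalings.

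The method was tested on simulated counts drawn from the means and library sizes of these data, with 200 of 26268 genes changed. For yolk against whole embryo at 48 hpf 35% of 100 genes changed 2-fold and 75% of 100 genes changed 4-fold were recovered, and 4.35% of 115 calls were false. For yolk at 48 against 26 hpf these shares were 36%, 79% and 3.36% of 119 calls. With so few genes changed, these shares do not give the detection rate in the data.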

Results

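Transcript counts of 32 zebrafish libraries were compared, 4 each of whole embryos and of yolk tissue at 6, 10, 26 and 48 hours post fertilization (hpf). The series concerns the supply of yolk lipid to the embryo through Hnf4 factors and lipoproteins, so the comparisons ask where and when genes of this pathway were transcribed. Of 36109 genes 26268 were tested. The first principal component held 46% of the variance and the second 17.8%. The 10 most abundant genes took 10.64% of the counts in yolk at 6 hpf and 22.99% at 48 hpf, against 7.342% and 9.397% in whole embryos. In yolk, apobb.1 alone went from 0.1412% of all counts at 6 hpf to 7.386% at 26 hpf and 6.523% at 48 hpf.

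Levels are TMM-scaled CPM, counts of a gene at a common library size, as mean ± SD over n = 4 libraries, with the first-named group first. Gene calls come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and medians are log2 differences. Members of each list were also counted when adjusted over the list alone, and that pair of counts, up and down, is given wherever it differed from the count over all genes. The labels do not say whether replicates were separate clutches, so each p-value measures spread between these samples. Scaling by library totals alone moved the median log2 difference between yolk and whole embryos by -0.37, -0.87, -1.06 and -0.61 at the 4 ages. "Without replicate 1" means without yolk replicate 1 of 26 hpf, which was singled out after the values were seen. Closely related genes, such as apobb.1 and apobb.2 or the globins, are uncertain as single genes because counting could split their reads.

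**Figure D1:**
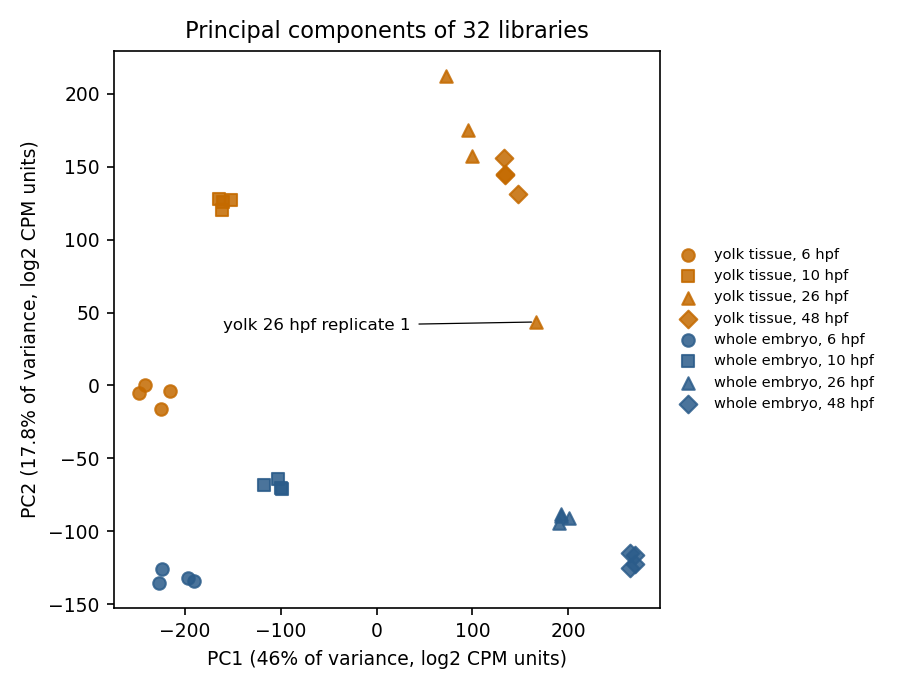
Principal components of log2 CPM for the 32 libraries, with the first component (46% of the variance) on the horizontal axis and the second (17.8%) on the vertical axis. Each point is 1 library, with color for tissue and shape for age in hpf.

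At 6 hpf transcripts of the lipoprotein pathway already took a far larger share of the counts in yolk than in whole embryos. Hnf4a encodes a nuclear receptor of liver and gut, and mttp the protein that loads lipid onto apolipoprotein B. Higher in yolk were hnf4a (12-fold, 1660 ± 143 against 138 ± 30.6 CPM) and mttp (12-fold, 8850 ± 492 against 735 ± 129 CPM), with adjusted p = 2.3e-12 and 8.3e-13. The same held for pla2g12b (12-fold, 2130 ± 330 against 178 ± 46.1 CPM) and dgat2 (12.1-fold, 199 ± 77.3 against 16.4 ± 6.49 CPM). Genes of dividing and patterned embryonic cells were lower, among them pcna (4.2-fold, 242 ± 36.6 against 1020 ± 153 CPM) and tbxta (20.3-fold, 22 ± 13.2 against 446 ± 29 CPM). In all, 6514 genes were higher and 7199 lower in yolk, and 5027 and 8841 under library totals.

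Higher in yolk were 10 of 15 apolipoproteins, and 1 was lower (median 3.02, camera adjusted p = 3.7e-05, adjusted p = 0.26 with an estimated correlation, 11 and 1 adjusted over the list alone). Examples were apoba (11.4-fold), apobb.1 (10.4-fold), apoa1b (8.12-fold) and apoeb (4.12-fold, 18000 ± 2530 against 4380 ± 635 CPM), and apoc1 (1.77-fold, 246 ± 8.44 against 436 ± 91.4 CPM) was the exception. Lipoprotein assembly genes followed with 14 of 21 higher and 3 lower (median 1.99, 1.98 with 0-count genes at their bound, camera adjusted p = 3.7e-05, adjusted p = 0.26 with an estimated correlation, 13 and 1 with a replicate block). Among Hnf4-family and hepatic transcription factors 15 of 23 were higher and 6 lower (median 2.42, camera adjusted p = 0.0014, adjusted p = 0.29 with an estimated correlation, 12 and 3 with a replicate block). The higher ones included gata6 (9.67-fold, 2850 ± 519 against 295 ± 59.1 CPM) and onecut1 (12.7-fold), the lower ones foxa1 (12.9-fold). No count of hnf4g was found in yolk, and the gene was at least 7.79-fold lower there. The focal list of Hnf4 and lipoprotein genes had 16 of 19 members higher and 2 lower (median 3.25, camera adjusted p = 9.3e-09, adjusted p = 0.26 with an estimated correlation).

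Markers of the early yolk syncytial layer, the nucleated rim of the yolk cell, were enriched in 6 of 9 cases and lower in 1 (median 2.19, camera adjusted p = 0.0036, adjusted p = 0.22 with an estimated correlation). They were led by mxtx1 (12.7-fold, 407 ± 76.2 against 32 ± 4.6 CPM) and sox32 (7.71-fold, 1140 ± 83.1 against 148 ± 22.3 CPM). Secreted plasma proteins leaned to yolk with 17 of 29 higher and 1 lower (median 1.97, camera adjusted p = 0.00012, adjusted p = 0.29 with an estimated correlation, 18 and 1 adjusted over the list alone). Examples were fetub (11.2-fold, 7800 ± 1450 against 698 ± 160 CPM) and tfa (9.37-fold). The lysosome contributed 22 of 27 higher genes and 1 lower (median 1.96, camera adjusted p = 2.6e-08, adjusted p = 0.26 with an estimated correlation). Its members ctsc (9.17-fold, 20800 ± 2350 against 2270 ± 376 CPM), npc2 (10.5-fold) and lamp2 (10.3-fold) illustrate the size of the difference. In gluconeogenesis and glycogen 7 of 18 were higher and 1 lower (median 0.94, camera adjusted p = 0.013, adjusted p = 0.32 with an estimated correlation). An example was pck2 (9.73-fold, 6300 ± 933 against 647 ± 154 CPM). Single nutrient carriers stood out too, such as slc7a8a (13-fold, 13300 ± 2040 against 1020 ± 285 CPM) for amino acids and cd36 (12-fold) and scarb1 (8.89-fold) for lipids. All 12 mitochondrially encoded transcripts were higher (median 1.25, camera adjusted p = 3.7e-05, adjusted p = 0.29 with an estimated correlation).

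Lists of embryonic cells went the other way. All 20 proliferation genes were lower (median -2.32, camera adjusted p = 1.4e-12, adjusted p = 0.19 with an estimated correlation), with mcm6 (28.5-fold, 16.8 ± 9.89 against 481 ± 71.7 CPM) the largest. Gastrula patterning genes were lower in 13 of 15 cases and higher in 2 (median -3.05, camera adjusted p = 0.00057, adjusted p = 0.19 with an estimated correlation). A lower member was otx2b (25.4-fold), and vent (5.12-fold) was higher. Of epidermal and enveloping layer markers 1 of 20 was higher and 17 lower (median -3.48, camera adjusted p = 0.00021, adjusted p = 0.39 with an estimated correlation). Among them krt92 (15.8-fold, 51.5 ± 60 against 812 ± 147 CPM) was lower and anxa1a (10.2-fold, 5440 ± 507 against 532 ± 113 CPM) higher. Ribosomal protein genes were lower in 48 of 78 cases and higher in 2 (median -0.49, camera adjusted p = 0.00039, adjusted p = 0.66 with an estimated correlation, 2 and 50 adjusted over the list alone, 2 and 27 with a replicate block). An example was rplp0 (2.02-fold, 452 ± 29 against 912 ± 238 CPM). The largest ratios outside the lists belonged to nptx2b (21-fold), hcn5 (18.1-fold), rps6ka2 (17.7-fold), tgfb2 (17.7-fold) and art4 (16-fold), all higher in yolk. At the lower end stood irx1b (102-fold), tlnrd1 (85-fold), pcdh18b (79.2-fold), mn1a (66.9-fold) and snai2 (66.4-fold).

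By 10 hpf, at the close of gastrulation, apolipoprotein transcripts were among the most abundant in yolk. Higher there were apobb.1 (12.9-fold, 27200 ± 2970 against 2100 ± 494 CPM), apoa1b (17.6-fold, 15300 ± 2300 against 871 ± 118 CPM) and apoeb (8.63-fold, 28200 ± 1070 against 3270 ± 240 CPM). The regulators and assembly genes kept their distance, with hnf4a (16.3-fold, 398 ± 49.5 against 24.4 ± 4.01 CPM), mttp (15.5-fold, 2960 ± 320 against 191 ± 35.4 CPM) and pla2g12b (16.5-fold, 5510 ± 242 against 334 ± 33.6 CPM). Keratin and neural transcripts were far lower, as for krt4 (62.7-fold, 81.3 ± 20 against 5100 ± 473 CPM). Altogether 6448 genes were higher and 7859 lower in yolk, and 3931 and 12344 under library totals.

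For apolipoproteins 13 of 15 were higher (median 3.95, camera adjusted p = 2.2e-08, adjusted p = 0.089 with an estimated correlation). In the focal list 18 of 19 were higher (median 3.95, camera adjusted p = 1.4e-12, adjusted p = 0.089 with an estimated correlation). Assembly genes were higher in 15 of 21 cases and lower in 3 (median 2.95, camera adjusted p = 2.9e-06, adjusted p = 0.11 with an estimated correlation). Among them cideb (17-fold) and dgat2 (15.4-fold) were higher. Among transcription factors 17 of 23 were higher and 2 lower (median 2.51, camera adjusted p = 3.8e-07, adjusted p = 0.089 with an estimated correlation), and here cebpa (17.2-fold) was higher and hnf1bb (49.7-fold) lower. Plasma proteins had 24 of 29 members higher and 1 lower (median 3.91, 3.85 with 0-count genes at their bound, camera adjusted p = 4e-10, adjusted p = 0.089 with an estimated correlation, 25 and 1 adjusted over the list alone). An example was fetub (16.9-fold, 23900 ± 542 against 1420 ± 126 CPM). Yolk syncytial layer markers still stood out, as 6 of 9 were higher and 1 lower (median 2.95, camera adjusted p = 0.00037, adjusted p = 0.089 with an estimated correlation).

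Metabolic lists leaned the same way. In the lysosome 21 of 27 were higher (median 2.8, camera adjusted p = 6.5e-12, adjusted p = 0.089 with an estimated correlation). Examples were ctsc (16.3-fold, 26900 ± 2870 against 1660 ± 221 CPM), ctsba (16.5-fold) and psap (14.6-fold). Gluconeogenesis and glycogen genes were higher in 13 of 18 cases and lower in 1 (median 2.68, camera adjusted p = 2.3e-05, adjusted p = 0.089 with an estimated correlation, 14 and 1 adjusted over the list alone). Among them pck2 (15.6-fold, 16400 ± 2250 against 1050 ± 163 CPM) and fbp1b (16.1-fold) were higher and pygmb (32.5-fold) lower. Genes of beta-oxidation, which burns fatty acids, were higher in 14 of 22 cases and lower in 3 (median 1.14, camera adjusted p = 0.00036, adjusted p = 0.11 with an estimated correlation). An example was slc25a20 (11.6-fold). In fatty acid and triglyceride synthesis 13 of 25 were higher and 7 lower (median 1.08, camera adjusted p = 0.027, adjusted p = 0.23 with an estimated correlation, 14 and 7 adjusted over the list alone). Among them mogat2 (16.4-fold) was higher and acaca (26.8-fold) lower. All 12 mitochondrially encoded transcripts were again higher (median 1.29, camera adjusted p = 1.2e-05, adjusted p = 0.22 with an estimated correlation).

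Without exception the 20 proliferation genes were lower (median -1.92, camera adjusted p = 1.7e-11, adjusted p = 0.089 with an estimated correlation). An example was mcm2 (7.27-fold, 49.5 ± 7.67 against 360 ± 30.1 CPM). Among epidermal markers 1 of 20 was higher and 18 lower (median -5.42, camera adjusted p = 1.3e-06, adjusted p = 0.22 with an estimated correlation). Among them agr1 (167-fold) was lower and anxa1a (15.3-fold) higher. Neural markers were lower in 14 of 20 cases and higher in 1 (median -3.17, camera adjusted p = 0.00072, adjusted p = 0.32 with an estimated correlation, 2 and 15 adjusted over the list alone). Among them pax6a (108-fold) and zic1 (61.3-fold) were lower. Macrophage markers were mixed, as 7 of 15 were higher and 3 lower (median 0, camera adjusted p = 0.55, 2 and 2 with a replicate block). Among them ctss2.1 (18.7-fold) was higher and lcp1 (49.9-fold) lower. Outside the lists, the largest ratios in yolk belonged to rhcga (30.8-fold), ednrab (26.7-fold), rln3a (26.7-fold), slc52a3 (23.4-fold) and epdl2 (22.6-fold). The deepest deficits were those of en2a (187-fold), lhx2b (157-fold), rx3 (139-fold) and camk2d1 (115-fold).

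After segmentation every apolipoprotein tested was higher in yolk. Examples were apobb.1 (24.1-fold, 113000 ± 37400 against 4690 ± 832 CPM), apoa1a (33.7-fold, 44400 ± 14500 against 1320 ± 101 CPM) and apoa4b.1 (34.5-fold). The Hnf4 paralogs followed with hnf4a (20.3-fold, 72.4 ± 37.3 against 3.56 ± 0.894 CPM) and hnf4b (26.8-fold, 176 ± 83.4 against 6.57 ± 1.07 CPM), and mttp was 20.9-fold higher. Transcripts of muscle and nerve were lower, but replicate 1 of yolk carried much more of them than replicates 2 to 4. For elavl3 the levels were 63.1 ± 80.4 against 437 ± 30.6 CPM, and the yolk level without replicate 1 was 23.2 ± 13.1. Here 5406 genes were higher and 6648 lower. The counts were 2633 and 14969 under library totals, 5655 and 4109 when only these 8 libraries were fitted, and 5309 and 4420 when these were fitted with a replicate block.

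Apolipoproteins were higher in 15 of 15 cases (median 4.82, camera adjusted p = 1.3e-15, adjusted p = 0.021 with an estimated correlation). The focal list was so in 18 of 19 (median 4.71, camera adjusted p = 1.1e-20, adjusted p = 0.021 with an estimated correlation). Assembly genes numbered 19 of 21 higher and 1 lower (median 2, camera adjusted p = 1.5e-12, adjusted p = 0.021 with an estimated correlation), led by creb3l3b (35.1-fold), pla2g12b (26.2-fold, 6400 ± 2340 against 244 ± 26 CPM) and dgat2 (22.4-fold). Among transcription factors 13 of 23 were higher and 1 lower (median 1.72, camera adjusted p = 1.2e-07, adjusted p = 0.031 with an estimated correlation). The plasma protein list had 27 of 29 higher and 2 lower (median 4.7, camera adjusted p = 1.6e-15, adjusted p = 0.021 with an estimated correlation). Examples were tfa (32.6-fold, 24400 ± 9230 against 750 ± 148 CPM) and fetub (29.9-fold). In the lysosome 23 of 27 were higher and 1 lower (median 3.48, camera adjusted p = 3.9e-20, adjusted p = 0.021 with an estimated correlation). Examples were npc2 (33.1-fold, 4680 ± 2510 against 141 ± 45 CPM) and ctsla (28.7-fold, 16800 ± 5570 against 587 ± 33.6 CPM). Gluconeogenesis genes were higher in 13 of 18 cases and lower in 2 (median 2.09, camera adjusted p = 9.4e-07, adjusted p = 0.031 with an estimated correlation). Examples were g6pca.2 (31.4-fold) and fbp1b (31.8-fold).

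Blood lists also had more members higher than lower in yolk under TMM, and whether blood over the yolk accounts for this was not tested. Macrophage and leukocyte markers were higher in 11 of 15 cases and lower in 1 (median 2.12, camera adjusted p = 3.2e-05, adjusted p = 0.021 with an estimated correlation). Examples were ctss2.1 (58.9-fold, 3620 ± 1300 against 61.4 ± 15.4 CPM) and mpx (4.33-fold). Among erythroid markers 10 of 16 were higher (median 1.5, camera adjusted p = 0.012, adjusted p = 0.39 with an estimated correlation, 11 and 0 adjusted over the list alone, 0 and 0 under library totals). An example was hbbe3 (3.06-fold, 922 ± 538 against 301 ± 21.5 CPM). Cholesterol synthesis genes were higher in 9 of 23 cases and lower in 2 (median 0.36, camera adjusted p = 0.0072, adjusted p = 0.14 with an estimated correlation, 10 and 4 adjusted over the list alone, 10 and 0 with a replicate block, 7 and 12 under library totals with a median of -0.72). Among them fdps (17.4-fold) was higher.

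Lists of body tissue were lower. Muscle markers were lower in 12 of 24 cases (median -2.74, camera adjusted p = 1.6e-06, adjusted p = 0.27 with an estimated correlation, 0 and 14 adjusted over the list alone, 0 and 19 with a replicate block, 0 and 24 without replicate 1 with a median of -6.42). For myhz2 the levels were 104 ± 207 against 1210 ± 317 CPM, and 1.05 ± 1.03 in yolk without replicate 1. All 20 neural markers were lower (median -2.59, camera adjusted p = 1.9e-06, adjusted p = 0.14 with an estimated correlation, 0 and 20 without replicate 1 with a median of -4.15). So were all 20 proliferation genes (median -0.94, camera adjusted p = 7.4e-07, adjusted p = 0.14 with an estimated correlation), among them pcna (2.04-fold, 272 ± 100 against 557 ± 28.1 CPM). Epidermal markers were lower in 17 of 20 cases and higher in 2 (median -2.01, camera adjusted p = 0.002, adjusted p = 0.39 with an estimated correlation, 2 and 18 adjusted over the list alone, 2 and 8 with a replicate block). Among them krt4 (4.72-fold, 2410 ± 1860 against 11400 ± 664 CPM) was lower. Lens markers were lower in 4 of 12 cases and higher in 1 (median -2.98, camera adjusted p = 0.014, adjusted p = 0.45 with an estimated correlation, 1 and 3 adjusted over the list alone, 1 and 10 with a replicate block, 1 and 9 without replicate 1 with a median of -6.1). Among them cryaa (7.53-fold) was higher. Other large ratios in yolk were those of epd (69.7-fold), bco2l (54.4-fold), elovl8a (50.5-fold) and ddr2b (50-fold). On the low side were napba (14.5-fold), capn3a (13.4-fold) and flrt1b (12-fold).

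**Figure D2:**
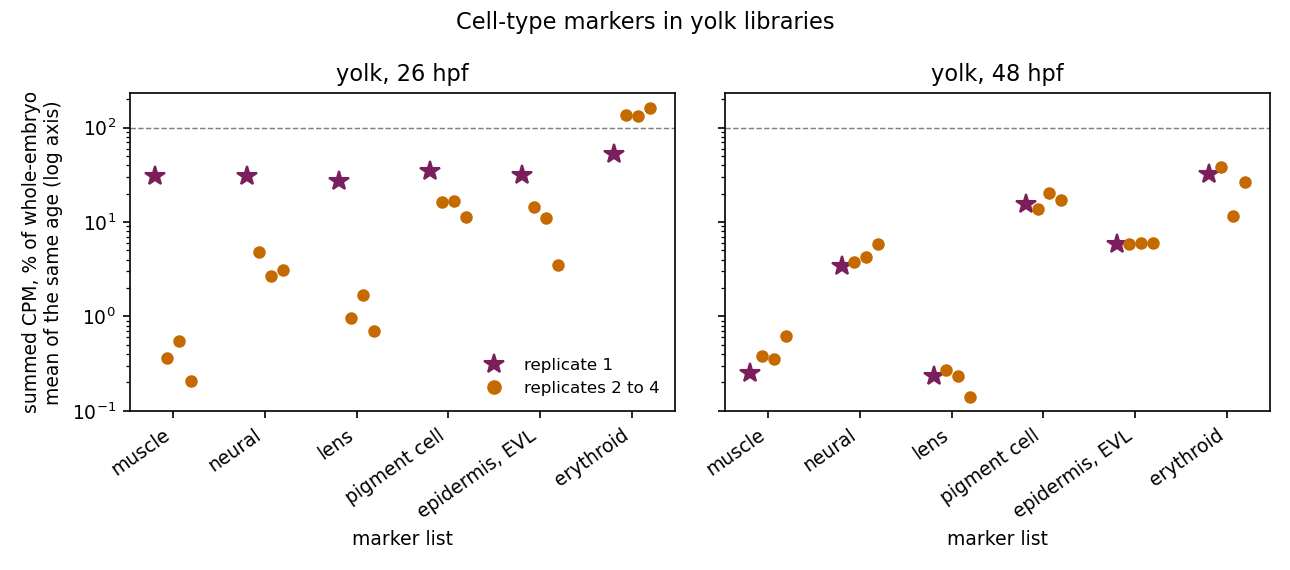
Summed CPM of marker lists in single yolk libraries at 26 hpf (left) and 48 hpf (right), as percent of the whole-embryo mean of the same age on a log axis. Stars mark replicate 1 and circles replicates 2 to 4, and the dashed line marks 100%.

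At 48 hpf every member of the focal list was higher in yolk, including hnf4a (21.2-fold, 155 ± 4.18 against 7.28 ± 1.05 CPM) and hnf4g (14.7-fold, 10.1 ± 1.6 against 0.683 ± 0.158 CPM). Leading apolipoproteins were apobb.1 (25.1-fold, 71700 ± 2730 against 2860 ± 603 CPM), apoa1b (28.5-fold, 41900 ± 8010 against 1470 ± 330 CPM), apoa2 (28.6-fold, 28000 ± 3550 against 982 ± 164 CPM) and apoc1 (30.5-fold, 11500 ± 1120 against 375 ± 84.1 CPM). Muscle, neural, lens and skin transcripts were far lower in yolk, as for myhz1.1 (544-fold, 18.1 ± 16.6 against 9870 ± 595 CPM) and actc1b (171-fold, 62.4 ± 22.2 against 10700 ± 1080 CPM). A total of 5998 genes were higher and 7230 lower in yolk, and 3029 and 11166 under library totals.

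All 15 apolipoproteins were higher (median 4.8, camera adjusted p = 7.8e-14, adjusted p = 0.026 with an estimated correlation). So were all 19 focal genes (median 4.64, camera adjusted p = 5.7e-19, adjusted p = 0.026 with an estimated correlation). Among assembly genes 17 of 21 were higher and 1 lower (median 1.57, camera adjusted p = 2.2e-08, adjusted p = 0.057 with an estimated correlation, 18 and 1 adjusted over the list alone). Among them pla2g12b (28.5-fold, 3840 ± 500 against 135 ± 31.7 CPM) and dgat2 (24-fold) were higher and tm6sf2 (27.9-fold) lower. Transcription factors were higher in 20 of 23 cases (median 3.19, camera adjusted p = 6e-11, adjusted p = 0.026 with an estimated correlation, 20 and 1 adjusted over the list alone, 20 and 2 with a replicate block). An example was hnf4b (19.8-fold). Plasma proteins were higher in 27 of 29 cases (median 4.6, camera adjusted p = 1.2e-15, adjusted p = 0.026 with an estimated correlation). Examples were serpina1 (32.3-fold), tfa (26.9-fold) and fetub (26.6-fold). Of the syncytial layer markers 6 of 9 were higher and 1 lower (median 2.88, camera adjusted p = 0.00042, adjusted p = 0.044 with an estimated correlation).

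Cholesterol synthesis formed a group of its own, in which 13 of 23 were higher (median 1.24, camera adjusted p = 5.5e-06, adjusted p = 0.026 with an estimated correlation). Members were fdps (9.1-fold), idi1 (5.27-fold) and hmgcs1 (3.66-fold). In the lysosome 22 of 27 were higher and 2 lower (median 2.22, camera adjusted p = 1.8e-11, adjusted p = 0.085 with an estimated correlation). An example was ctsla (21.3-fold, 6900 ± 2600 against 325 ± 99.5 CPM). Beta-oxidation genes were higher in 16 of 22 cases and lower in 2 (median 1.02, camera adjusted p = 4.6e-05, adjusted p = 0.078 with an estimated correlation). Among them cpt1b (12.6-fold) was lower. Gluconeogenesis gave 12 of 18 higher and 2 lower (median 1.17, camera adjusted p = 0.00021, adjusted p = 0.11 with an estimated correlation, 13 and 5 with a replicate block). An example was g6pca.2 (29.8-fold). Chaperones gave 13 of 27 and 1 (median 0.57, camera adjusted p = 0.00016, adjusted p = 0.21 with an estimated correlation, 14 and 1 adjusted over the list alone, 23 and 1 with a replicate block, 8 and 5 under library totals with a median of -0.03). Amino acid transporters gave 12 of 20 and 4 (median 1, camera adjusted p = 0.0034, adjusted p = 0.14 with an estimated correlation). For lipid uptake the split was 15 of 29 higher and 6 lower (median 0.44, camera adjusted p = 0.015, adjusted p = 0.13 with an estimated correlation, 16 and 6 adjusted over the list alone, 16 and 10 with a replicate block, 13 and 10 under library totals with a median of -0.17). For triglyceride synthesis it was 13 of 25 and 6 (median 0.51, camera adjusted p = 0.021, adjusted p = 0.17 with an estimated correlation, 9 and 9 under library totals with a median of -0.11). Lipases had 4 of 9 higher and 1 lower (median 1.18, camera adjusted p = 0.1, 3 and 3 under library totals). All 12 mitochondrially encoded genes were higher (median 0.78, camera adjusted p = 0.00047, adjusted p = 0.23 with an estimated correlation, 0 and 0 under library totals). So were 55 of 78 ribosomal protein genes (median 0.45, camera adjusted p = 1.9e-07, adjusted p = 0.37 with an estimated correlation, 61 and 0 adjusted over the list alone, 1 and 0 under library totals with a median of -0.17).

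Proliferation genes had changed sides, since 12 of 20 were higher (median 0.45, camera adjusted p = 0.0084, adjusted p = 0.38 with an estimated correlation, 13 and 0 adjusted over the list alone, 0 and 2 under library totals with a median of -0.16). Higher members were mcm2 (1.62-fold, 140 ± 5.08 against 86.1 ± 6.32 CPM) and pcna (1.51-fold), whose log2 under library totals was -0.02. Endothelial markers were higher in 4 of 14 cases (median 0.76, camera adjusted p = 0.04, adjusted p = 0.14 with an estimated correlation, 3 and 0 adjusted over the list alone, 11 and 0 with a replicate block, 0 and 0 under library totals). Examples were etv2 (2.57-fold) and kdr (1.78-fold). Maternal oocyte genes were higher in 10 of 17 (median 2.28, camera adjusted p = 0.0041, adjusted p = 0.087 with an estimated correlation, 2 and 0 with a replicate block). Macrophage markers were split, as 3 of 15 were higher and 3 lower (median 0.45, camera adjusted p = 0.23, 2 and 3 adjusted over the list alone, 7 and 3 with a replicate block, 2 and 3 under library totals with a median of -0.16). Erythroid markers were lower in 8 of 16 cases (median -1.32, camera adjusted p = 0.035, adjusted p = 0.42 with an estimated correlation, 0 and 13 with a replicate block). An example was klf17 (5.72-fold). Hatching gland markers had 1 of 8 higher and 3 lower (median -2.78, -1.73 with 0-count genes at their bound, camera adjusted p = 0.26).

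The lowest list median of yolk against whole embryo was that of lens, where all 12 were lower (median -9.74, camera adjusted p = 4e-06, adjusted p = 0.17 with an estimated correlation). An example was crybb1l1 (2380-fold, 0.318 ± 0.371 against 789 ± 24.3 CPM). The near-identical crygm2d2, crygm2d21, crygm2d15 and crygm2d6 had 0 counts in yolk. They were at least 5610-fold, at least 5850-fold, at least 3030-fold and at least 1270-fold lower, while crygm2d13 had few counts (ratio 9820, 95% counting interval 2720 to 81100). Muscle markers were lower in 21 of 24 cases (median -7.33, camera adjusted p = 9.1e-07, adjusted p = 0.23 with an estimated correlation). Neural markers were lower in 19 of 20 (median -4.57, camera adjusted p = 3.1e-08, adjusted p = 0.11 with an estimated correlation). An example was elavl3 (25.7-fold, 29.8 ± 12.6 against 769 ± 30.6 CPM). Epidermal markers were lower in 15 of 20 and higher in 2 (median -4.76, camera adjusted p = 1.2e-05, adjusted p = 0.2 with an estimated correlation, 3 and 16 adjusted over the list alone). Among them krt4 (34.6-fold, 322 ± 12.3 against 11100 ± 1300 CPM) and krt5 (158-fold) were lower. Pigment markers gave 10 of 12 lower and 1 higher (median -2.32, camera adjusted p = 0.0031, adjusted p = 0.095 with an estimated correlation). Among them gch2 (27.8-fold) and dct (7.32-fold) were lower. Gastrula patterning genes gave 8 of 15 lower and 2 higher (median -1.72, camera adjusted p = 0.026, adjusted p = 0.17 with an estimated correlation, 2 and 9 adjusted over the list alone). Further genes far higher in yolk were slc2a5 (48.3-fold), c3a.5 (44.9-fold), leg1.2 (39.9-fold), hpxa (34.5-fold) and urad (34-fold).

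**Figure D3:**
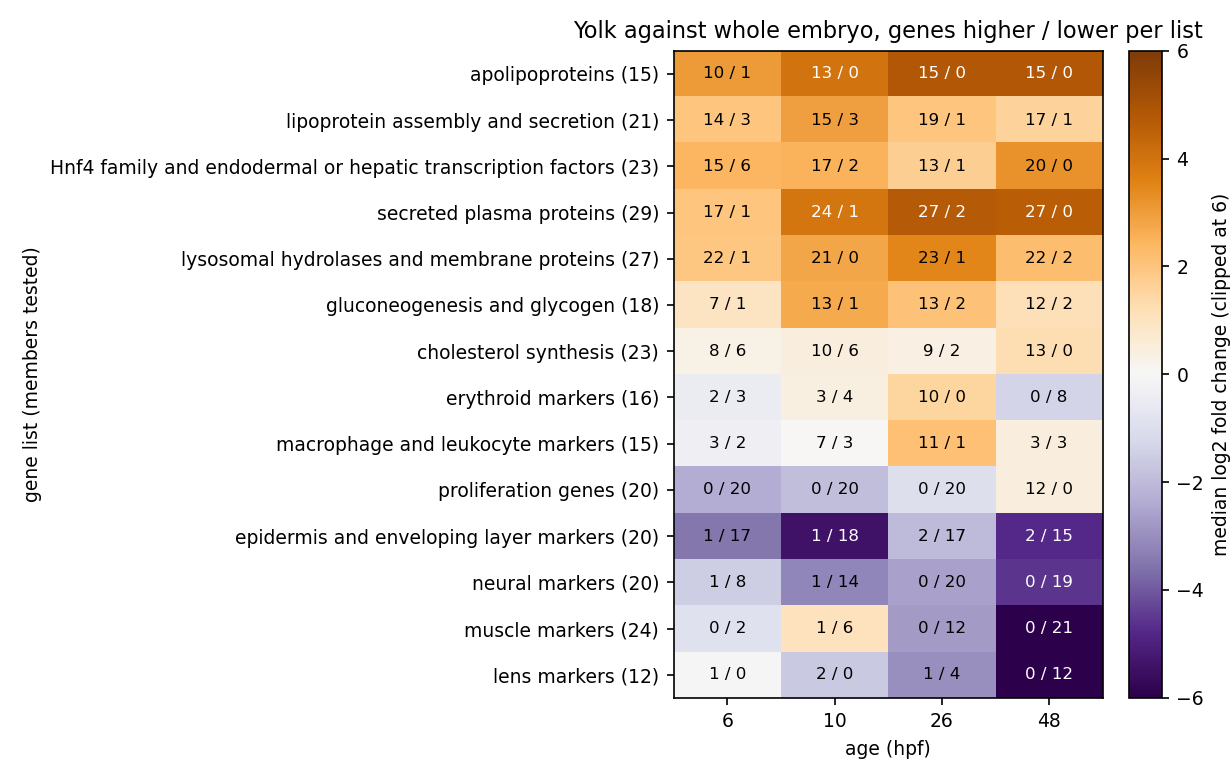
Median log2 fold change of yolk against whole embryo for gene lists (vertical axis, members tested in parentheses) at each age in hpf (horizontal axis), with genes higher / lower printed in each cell. Of the lists shown, the medians of cholesterol synthesis at 6, 10 and 26 hpf and of proliferation and macrophage genes at 48 hpf changed sign under library totals.

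Across the 4 ages 1716 genes were higher in yolk each time, where independent lists would give 75. Lower at every age were 1249, against 150. Under library totals these numbers were 953 and 3594.

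Between 6 and 10 hpf the yolk gained apolipoprotein transcripts and lost those of hnf4a and mttp. Rises were apobb.1 (15.3-fold, 27200 ± 2970 against 1770 ± 571 CPM), apoba (16.4-fold, 1760 ± 326 against 107 ± 39.7 CPM) and apoa4b.1 (45.2-fold). Falls were hnf4a (4.19-fold, 398 ± 49.5 against 1660 ± 143 CPM) at adjusted p = 5.4e-08 and mttp (2.99-fold, 2960 ± 320 against 8850 ± 492 CPM). In the same interval 6775 genes rose and 6140 fell.

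Among apolipoproteins 12 of 15 rose and 1 fell (median 2.98, camera adjusted p = 1.4e-05, adjusted p = 0.33 with an estimated correlation). In the focal list 15 of 19 rose and 3 fell (median 2.98, camera adjusted p = 3.8e-05, adjusted p = 0.57 with an estimated correlation). Assembly genes were mixed, as 11 of 21 rose and 5 fell (median 0.62, camera adjusted p = 0.1). Among them cideb (30.4-fold) and pla2g12b (2.58-fold) rose. Transcription factors were mixed as well: 14 of 23 rose and 7 fell (median 1.16, camera adjusted p = 0.07). Among them foxa1 (350-fold, 14 ± 3.03 against 0.0379 ± 0.0442 CPM) rose and gata6 (2.19-fold) fell. Plasma proteins rose in 23 of 29 cases (median 3.7, 3.33 with 0-count genes at their bound, camera adjusted p = 7.4e-09, adjusted p = 0.19 with an estimated correlation). An example was serpina1l (85.7-fold). In beta-oxidation 15 of 22 rose and 2 fell (median 1.49, camera adjusted p = 0.00017, adjusted p = 0.19 with an estimated correlation). Ribosomal protein genes rose in 68 of 78 cases and fell in 1 (median 0.88, camera adjusted p = 8.6e-11, adjusted p = 0.57 with an estimated correlation, 69 and 1 adjusted over the list alone).

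Maternal oocyte genes fell in 8 of 17 cases (median -1.35, camera adjusted p = 0.0026, adjusted p = 0.19 with an estimated correlation, 0 and 13 with a replicate block). An example was nanog (16-fold, 2.76 ± 0.336 against 44.4 ± 11 CPM). Among syncytial layer markers 2 of 9 rose and 5 fell (median -1.31, camera adjusted p = 0.15). Among them sox32 (28.6-fold, 39.8 ± 8.96 against 1140 ± 83.1 CPM) fell and slc40a1 (19.6-fold) rose. Endothelial markers rose in 8 of 14 cases and fell in 1 (median 1.5, camera adjusted p = 0.0078, adjusted p = 0.19 with an estimated correlation). Among them kdrl (21.4-fold) rose. Single genes moved far, as with slc43a2a (150-fold, 1090 ± 135 against 7.24 ± 2.63 CPM) up and pnp4a (45.2-fold, 29.7 ± 5.93 against 1340 ± 106 CPM) down. From 0 counts at 6 hpf rose hoxc8a (at least 1150-fold), hoxb10a (at least 1100-fold), efna3b (at least 579-fold) and ednrab (at least 470-fold), and lsp1 rose 2800-fold. The largest falls were those of hlx1 (at least 452-fold), lingo2b (1000-fold), tfec (332-fold), ntng2b (ratio 348, 95% counting interval 119 to 1690) and nptx2b (255-fold).

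From 10 to 26 hpf apolipoproteins rose further in yolk, with apobb.1 (4.15-fold, 113000 ± 37400 against 27200 ± 2970 CPM), apoba (7.9-fold) and apoc1 (7.33-fold). Against this, hnf4a (5.5-fold, 72.4 ± 37.3 against 398 ± 49.5 CPM) fell at adjusted p = 2.6e-09, and so did mttp (3.19-fold, 929 ± 508 against 2960 ± 320 CPM). Transcripts of blood cells appeared, such as slc4a1a (2600-fold, 306 ± 183 against 0.114 ± 0.0978 CPM) and mpx (905-fold, 72 ± 23.9 against 0.076 ± 0.107 CPM). In total 8760 genes rose and 6063 fell.

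Among apolipoproteins 13 of 15 rose (median 2.85, camera adjusted p = 1.5e-05, adjusted p = 0.19 with an estimated correlation, 14 and 0 adjusted over the list alone). In the focal list 11 of 19 rose and 3 fell (median 1.63, camera adjusted p = 0.047, adjusted p = 0.68 with an estimated correlation). Transcription factors fell in 11 of 23 cases and rose in 5 (median -0.84, mean 0.02, camera adjusted p = 0.039, adjusted p = 0.55 with an estimated correlation, 6 and 10 without replicate 1 and camera adjusted p = 0.076). Among them hnf4b (3.68-fold), gata5 (3.11-fold) and gata6 (3.62-fold) fell and cebpd (31-fold) rose. Syncytial layer markers fell in 7 of 9 cases and rose in 1 (median -1.86, camera adjusted p = 0.0033, adjusted p = 0.097 with an estimated correlation). Among them sox32 (916-fold) and mxtx1 (17.1-fold) fell. Plasma proteins rose in 20 of 29 cases and fell in 3 (median 1.44, camera adjusted p = 0.00064, adjusted p = 0.47 with an estimated correlation). Among them cp (1620-fold, 437 ± 177 against 0.267 ± 0.202 CPM) and c9 (477-fold) rose. Gastrula patterning genes fell in 13 of 15 cases (median -4.03, camera adjusted p = 3.3e-08, adjusted p = 0.0047 with an estimated correlation).

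Cell-type lists rose. Among erythroid markers 15 of 16 rose and 1 fell (median 8.09, 7.83 with 0-count genes at their bound, camera adjusted p = 2.9e-07, adjusted p = 0.14 with an estimated correlation). Among macrophage markers 11 of 15 rose and 1 fell (median 4.81, camera adjusted p = 8.6e-05, adjusted p = 0.034 with an estimated correlation). An example was mpeg1.1 (at least 299-fold). Endothelial markers rose in 11 of 14 cases and fell in 1 (median 3.2, camera adjusted p = 0.0013, adjusted p = 0.034 with an estimated correlation). Among them cdh5 (56.9-fold) rose. Hatching gland markers rose in 7 of 8 cases (median 5.9, 5.73 with 0-count genes at their bound, camera adjusted p = 0.0031, adjusted p = 0.12 with an estimated correlation). An example was he1.1 (336-fold, 550 ± 313 against 1.63 ± 1.71 CPM). Neural markers rose in 18 of 20 cases (median 4.34, camera adjusted p = 0.0013, adjusted p = 0.48 with an estimated correlation, 19 and 0 adjusted over the list alone, 14 and 1 without replicate 1 with a median of 2.39). Their sum over single libraries was 74.58 to 105.7 CPM without TMM scaling at 10 hpf, and at 26 hpf it was 959.6 in replicate 1 and 82.98 to 148.9 in the others. Of 24 muscle markers 20 rose and 1 fell (median 6.47, 6.3 with 0-count genes at their bound, camera adjusted p = 0.019, adjusted p = 0.68 with an estimated correlation, 21 and 1 adjusted over the list alone, 9 and 2 without replicate 1 with a median of 1.53 and camera adjusted p = 0.12). Among epidermal markers 16 of 20 rose and 3 fell (median 3.43, camera adjusted p = 0.03, adjusted p = 0.68 with an estimated correlation, 15 and 3 without replicate 1 and camera adjusted p = 0.068). From 0 counts at 10 hpf rose hbbe3 (at least 28500-fold), myh7 (at least 4760-fold), myl7 (at least 2500-fold), cmlc1 (at least 1600-fold) and abi3bpb (at least 1490-fold). The largest falls outside the lists were il23r (1270-fold), atg16l2 (ratio 1360, 95% counting interval 244 to 53800), dand5 (ratio 866, 95% counting interval 240 to 7160) and pcsk5a (635-fold).

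Between 26 and 48 hpf the direction of hnf4a turned, since hnf4a (2.14-fold, 155 ± 4.18 against 72.4 ± 37.3 CPM) rose at adjusted p = 0.0011 with hnf4g (9.12-fold, 10.1 ± 1.6 against 1.1 ± 0.552 CPM). On the other side, mttp (2.46-fold, 377 ± 63.3 against 929 ± 508 CPM) and apoeb (2.84-fold, 9460 ± 291 against 26900 ± 11000 CPM) fell. For apobb.1 the change of log2 -0.65 did not pass (adjusted p = 0.051), and without replicate 1 it was -0.85 at adjusted p = 0.0073. Lysosomal proteases fell steeply, such as ctsc (16.3-fold, 86.7 ± 21.4 against 1420 ± 696 CPM) and ctsh (37.8-fold, 16.9 ± 6.19 against 640 ± 285 CPM). In this step 3163 genes rose and 4235 fell, against 5986 and 2626 under library totals.

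Genes of the lysosome, which breaks down yolk protein, fell in 22 of 27 cases (median -1.37, camera adjusted p = 8.3e-14, adjusted p = 0.19 with an estimated correlation). Assembly genes fell in 12 of 21 cases and rose in 1 (median -0.74, camera adjusted p = 0.0038, adjusted p = 0.34 with an estimated correlation). By contrast 3 of 15 apolipoproteins fell (median -0.29, camera adjusted p = 0.39, 0 and 2 adjusted over the list alone, 2 and 1 under library totals with a median of 0.16). In the focal list 2 of 19 rose and 5 fell (median -0.32, camera adjusted p = 0.39, 2 and 6 adjusted over the list alone, 4 and 2 under library totals with a median of 0.15, 2 and 6 without replicate 1 and camera adjusted p = 0.044). Among transcription factors 9 of 23 rose and 5 fell (median 0.29, camera adjusted p = 0.073, 10 and 7 adjusted over the list alone, 9 and 8 without replicate 1 with a median of 0.13). Among them nr5a2 (8.54-fold) rose and gata5 (2.28-fold) fell. Cholesterol synthesis genes rose in 10 of 23 cases and fell in 4 (median 0.64, camera adjusted p = 0.037, adjusted p = 0.34 with an estimated correlation, 11 and 4 without replicate 1 and camera adjusted p = 0.13). Among them hmgcra (10.4-fold) rose and acat2 (4.79-fold) fell.

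Epidermal markers fell in 13 of 20 cases (median -2.65, camera adjusted p = 1.8e-05, adjusted p = 0.34 with an estimated correlation, 1 and 13 adjusted over the list alone). Examples were krt4 (7.48-fold, 322 ± 12.3 against 2410 ± 1860 CPM) and cyt1 (49.9-fold). Erythroid markers fell in 11 of 16 cases (median -2.13, camera adjusted p = 7.6e-06, adjusted p = 0.29 with an estimated correlation, 0 and 12 adjusted over the list alone). An example was gata1a (20-fold). Macrophage markers fell in 6 of 15 and rose in 1 (median -1.19, camera adjusted p = 0.0013, adjusted p = 0.19 with an estimated correlation). Among them ctss2.1 (275-fold, 13.2 ± 5.49 against 3620 ± 1300 CPM) fell. Hatching gland markers fell in 4 of 8 and rose in 1 (median -3.87, camera adjusted p = 0.0053, adjusted p = 0.19 with an estimated correlation). Among them he1.1 (154-fold, 3.58 ± 1.86 against 550 ± 313 CPM), he1.2 (231-fold) and ctslb (1350-fold) fell. Endothelial markers rose in 8 of 14 and fell in 1 (median 1.1, camera adjusted p = 0.035, adjusted p = 0.19 with an estimated correlation). Among them cldn5b (5.2-fold) and cdh5 (3.28-fold) rose. For proliferation genes 1 of 20 rose (median 0, camera adjusted p = 0.45, 0 and 0 adjusted over the list alone, 7 and 0 without replicate 1 with a median of 0.26 and camera adjusted p = 0.044). For muscle markers 9 of 24 fell (median -3.07, camera adjusted p = 0.77, 0 and 13 adjusted over the list alone, 4 and 1 without replicate 1 with a median of 1.24). The largest rises elsewhere were plac8.1 (at least 482-fold), gpa33b (433-fold), lama3 (370-fold), sox8a (304-fold) and, from 1 count, ldlra (ratio 786, 95% counting interval 217 to 6490). The largest falls were hspb12 (ratio 1450, 95% counting interval 400 to 12000) and tnnc1a (227-fold).

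**Figure D4:**
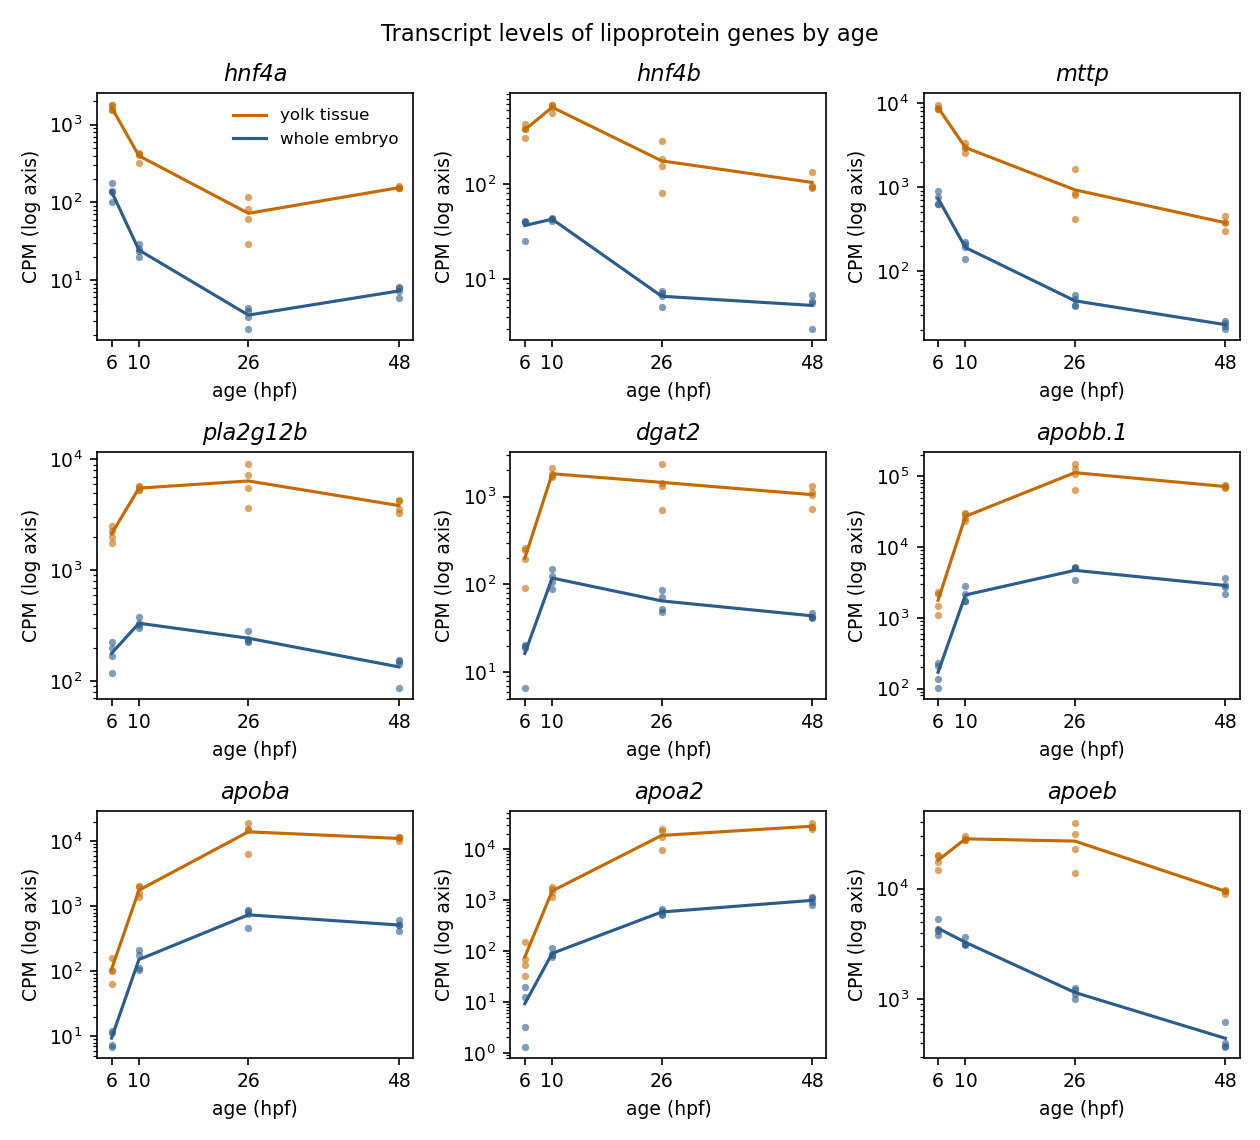
TMM-scaled CPM (log axis) of 9 lipoprotein genes by age in hpf. Points are single libraries and lines join the means of yolk tissue (orange) and whole embryo (blue).

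In whole embryos from 6 to 10 hpf transcripts of maternal oocyte genes declined. Other falls included tbxta (6.05-fold, 73.8 ± 7.03 against 446 ± 29 CPM), hnf4a (5.67-fold, 24.4 ± 4.01 against 138 ± 30.6 CPM) and mttp (3.85-fold, 191 ± 35.4 against 735 ± 129 CPM). Rises were apobb.1 (12.4-fold, 2100 ± 494 against 170 ± 59.7 CPM), elavl3 (29-fold, 48.2 ± 1.56 against 1.66 ± 0.572 CPM) and he1.1 (487-fold, 53.4 ± 8.67 against 0.106 ± 0.13 CPM). Over this step 5560 genes rose and 5255 fell, and 7539 and 2865 under library totals.

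Apolipoproteins rose in 8 of 15 cases and fell in 1 (median 1.54, camera adjusted p = 0.0013, adjusted p = 0.48 with an estimated correlation). For maternal oocyte genes 14 of 17 fell (median -2.52, camera adjusted p = 4e-06, adjusted p = 0.016 with an estimated correlation, 0 and 15 adjusted over the list alone). An example was h1m (15.9-fold). Proliferation genes fell in 14 of 20 cases and rose in 2 (median -0.67, camera adjusted p = 0.0013, adjusted p = 0.56 with an estimated correlation). Ribosomal protein genes rose in 61 of 78 cases (median 0.58, camera adjusted p = 3.2e-10, adjusted p = 0.56 with an estimated correlation, 64 and 0 adjusted over the list alone). Elsewhere rose hoxa3a (at least 527-fold), fli1a (ratio 810, 95% counting interval 224 to 6690) and nkx2.4b (ratio 1010, 95% counting interval 279 to 8340), and down went gcnt7 (562-fold), tfec (116-fold) and pnp4a (77.9-fold).

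From 10 to 26 hpf transcripts of differentiated tissue rose in whole embryos. Examples were actc1b (1280-fold, 4630 ± 194 against 3.62 ± 2 CPM) and atp2a1 (7600-fold) of muscle and elavl4 (220-fold, 55.9 ± 3.39 against 0.253 ± 0.101 CPM) of neurons. Further falls were those of hnf4a (6.84-fold, 3.56 ± 0.894 against 24.4 ± 4.01 CPM) and mttp (4.31-fold, 44.3 ± 6.58 against 191 ± 35.4 CPM). In all 7892 genes rose and 6823 fell.

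Muscle markers rose in 22 of 24 cases and fell in 1 (median 8.85, camera adjusted p = 1.9e-07, adjusted p = 0.4 with an estimated correlation). Neural markers rose in 13 of 20 (median 3.34, camera adjusted p = 0.00058, adjusted p = 0.45 with an estimated correlation). All 12 pigment markers rose (median 5.91, camera adjusted p = 6.1e-10, adjusted p = 0.0012 with an estimated correlation). Examples were tyr (186-fold) and dct (at least 2510-fold). Erythroid markers rose in 14 of 16 cases and fell in 1 (median 6.1, camera adjusted p = 1.1e-05, adjusted p = 0.3 with an estimated correlation). All 15 gastrula patterning genes fell (median -4.2, camera adjusted p = 1.7e-09, adjusted p = 0.0012 with an estimated correlation). An example was tbx16 (80.2-fold). Among apolipoproteins 12 of 15 rose and 1 fell (median 1.71, camera adjusted p = 0.0074, adjusted p = 0.47 with an estimated correlation). Among them apoeb (2.84-fold) fell. Elsewhere rose myhz1.3 (at least 221000-fold) and cavin4b (at least 9690-fold) from 0 counts, and down went szl (1460-fold), cdx1a (637-fold) and six7 (498-fold).

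In the last step cell-cycle transcripts declined in whole embryos, with pcna (3.07-fold, 181 ± 25.7 against 557 ± 28.1 CPM) and mcm2 (3.2-fold, 86.1 ± 6.32 against 275 ± 27 CPM). Lens transcripts rose, as for crygm2d2 (116-fold, 125 ± 8.35 against 1.07 ± 0.67 CPM) and cryaa (37.5-fold). Among lipoprotein genes hnf4a (2.04-fold, 7.28 ± 1.05 against 3.56 ± 0.894 CPM) rose. For apobb.1 (2860 ± 603 against 4690 ± 832 CPM) the fall passed at adjusted p = 0.04, and leaving out any 1 of 6 of these 8 libraries moved it to between 0.077 and 0.13. Calls numbered 3282 up and 2582 down, and 6411 and 5803 when only these 8 libraries were fitted.

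Proliferation genes fell in 19 of 20 cases (median -1.25, camera adjusted p = 1.5e-22, adjusted p = 0.042 with an estimated correlation, 0 and 20 adjusted over the list alone). Lysosomal genes fell in 10 of 27 and rose in 2 (median -0.37, camera adjusted p = 3e-04, adjusted p = 0.97 with an estimated correlation, 2 and 11 adjusted over the list alone). Among them ctsh (7-fold) and psap (2.66-fold) fell. Lens markers rose in 5 of 12 cases (median 3.02, camera adjusted p = 0.0028, adjusted p = 0.97 with an estimated correlation, 7 and 0 adjusted over the list alone). Among apolipoproteins 3 of 15 fell (median -0.18, camera adjusted p = 0.3, 0 and 5 adjusted over the list alone). Elsewhere col10a1a (ratio 5060, 95% counting interval 1400 to 41800), matn1 (558-fold) and crygm2d11 (at least 768-fold) rose, while wfikkn1 (60.5-fold) fell.

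The change from the early ages (6 and 10 hpf) to the late ages (26 and 48 hpf) was tested for a difference between tissues. It was more positive in yolk for apoc1 (log2 4.35, SE 0.23), apobb.1 (log2 1.08, SE 0.25) and pcna (log2 1.99, SE 0.16), each a log2 difference of changes. It was more negative for gch2 (log2 -5.45, SE 0.54) of the pigment list. Such differences passed for 7417 genes in the positive and 6040 in the negative direction.

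All 15 apolipoproteins changed more positively in yolk (median 1.43, camera adjusted p = 6e-04, adjusted p = 0.7 with an estimated correlation). So did 17 of 19 focal genes (median 1.15, camera adjusted p = 6e-04, adjusted p = 0.7 with an estimated correlation, 18 and 0 adjusted over the list alone). Examples were hnf4g (log2 4.63) and creb3l3a (log2 1.79). Plasma proteins were more positive in 21 of 29 cases (median 1.43, camera adjusted p = 0.0011, adjusted p = 0.7 with an estimated correlation). Proliferation genes were so in all 20 (median 1.84, camera adjusted p = 2.4e-11, adjusted p = 0.26 with an estimated correlation). An example was mcm6 (log2 3.41). Ribosomal protein genes were more positive in 66 of 78 cases (median 0.6, camera adjusted p = 2.1e-07, adjusted p = 0.81 with an estimated correlation, 68 and 0 adjusted over the list alone). Muscle markers were more negative in 18 of 24 cases and more positive in 1 (median -5, camera adjusted p = 6.7e-05, adjusted p = 0.79 with an estimated correlation, 1 and 19 adjusted over the list alone, 1 and 21 without replicate 1 with a median of -6.92). Lens markers were more negative in 10 of 12 (median -5.81, camera adjusted p = 0.00022, adjusted p = 0.7 with an estimated correlation, 0 and 11 adjusted over the list alone, 0 and 11 without replicate 1 with a median of -7.37). Pigment markers were so in 9 of 12 (median -3.04, camera adjusted p = 0.00018, adjusted p = 0.17 with an estimated correlation, 0 and 10 adjusted over the list alone). The largest single differences were olfml2a (log2 7.55), pou5f3 (log2 7.36) and fhl3b (log2 7.3) on the positive side and cx23 (log2 -9.95), lctla (log2 -9.49) and fgl1 (log2 -9.27) on the negative side. At most 3 counts in some group were found for hnf4g, olfml2a, fhl3b, cx23, lctla and fgl1, whose values therefore depend on the prior count of the fit.

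The step from 26 to 48 hpf differed between tissues most clearly in cell-cycle genes, which fell in whole embryos and not in yolk. The difference of changes was positive for pcna (log2 1.63, SE 0.23) and mcm2 (log2 1.66, SE 0.26). It was negative for ctsc (log2 -2.13, SE 0.32) and krt4 (log2 -2.87, SE 0.8). None of the apolipoproteins passed (median -0.13, camera adjusted p = 0.73 with the test pointing up, 0 by edgeR at an unadjusted p under 0.05 and 0 by DESeq2, 2 and 0 under library totals with a median of 0.45). Nor did any focal gene pass (median -0.12, mean 0.08, camera adjusted p = 0.55 with the test pointing up, 1 by edgeR at an unadjusted p under 0.05 and 0 by DESeq2, 3 and 0 under library totals with a median of 0.45). Passing in the positive direction were 2439 genes, with 3474 in the other, and 4500 and 1992 under library totals.

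Proliferation genes were more positive in yolk in 19 of 20 cases (median 1.33, camera adjusted p = 1.9e-16, adjusted p = 0.15 with an estimated correlation, 20 and 0 adjusted over the list alone). Lysosomal genes were more negative in 15 of 27 cases (median -0.89, camera adjusted p = 2.9e-05, adjusted p = 0.55 with an estimated correlation, 0 and 17 adjusted over the list alone). Erythroid markers were more negative in 12 of 16 (median -2.89, camera adjusted p = 2.3e-05, adjusted p = 0.44 with an estimated correlation, 0 and 16 adjusted over the list alone). Epidermal markers were more negative in 13 of 20 and more positive in 1 (median -2.61, camera adjusted p = 0.0044, adjusted p = 0.66 with an estimated correlation, 1 and 14 adjusted over the list alone). Macrophage markers were more negative in 5 of 15 (median -1.72, camera adjusted p = 0.00099, adjusted p = 0.2 with an estimated correlation, 0 and 7 adjusted over the list alone). Ribosomal protein genes gave 13 of 78 more positive and 1 more negative (median 0.46, camera adjusted p = 5e-08, adjusted p = 0.66 with an estimated correlation, 12 and 1 adjusted over the list alone, 25 and 1 without replicate 1 with a median of 0.53). Cholesterol synthesis genes gave 5 of 23 and 2 (median 0.41, camera adjusted p = 0.039, adjusted p = 0.51 with an estimated correlation, 7 and 2 adjusted over the list alone, 7 and 2 without replicate 1 and camera adjusted p = 0.11). Endothelial markers gave 4 of 14 and 1 (median 1.13, camera adjusted p = 0.04, adjusted p = 0.26 with an estimated correlation, 5 and 1 adjusted over the list alone, 5 and 1 without replicate 1 and camera adjusted p = 0.063). Examples were cldn5b (log2 1.78) and kdr (log2 -2.09). Lens markers were more negative in 9 of 12 cases (median -6.86, camera adjusted p = 0.00097, adjusted p = 0.66 with an estimated correlation, 0 and 11 adjusted over the list alone, 0 and 2 without replicate 1 with a median of -3.73). The largest single differences were muc13b (log2 6.01), uox (log2 5.86) and bin2a (log2 5.21) upward and gnb3a (log2 -11.46) and vsx1 (log2 -10.19) downward. Both of the latter had 2 counts over yolk at 48 hpf, so their values also depend on the prior count.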

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

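The tests of a label swap, of a few abundant genes and of dilution were chosen after the result was seen, while those of body RNA and of other splits of the libraries were chosen before. Within groups of 4 libraries, the highest or lowest library was singled out where its gap to the nearest other exceeded the 95% critical value of Dixon's ratio of gap to range. Of 161 such groups tested 15 met this, and chance alone picks about 1 in 20 groups, here 8.1.

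In yolk at 26 hpf replicate 1 stood far above the others in summed muscle markers (13370 CPM against 88.26 to 237.5), neural markers (959.6 against 82.98 to 148.9) and lens markers (138.8 against 3.551 to 8.69). A label swap was argued against by apobb.1, which stood at 75% of the mean of the other 3 yolk libraries, when no whole embryo exceeded 9.99%. Over 102 genes under 1% of the whole-embryo level in the other 3 libraries, replicate 1 reached a median of 33.1% with quartiles of 28.4 and 38.1%, a ratio of 1.34. The medians were 36% for 16 muscle genes and 27.6% for 5 lens genes, with 31.1% for 1 neural gene, and such a common share is consistent with body RNA in this library. No biological explanation was tested, since the design holds no group that sets this replicate apart.

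In yolk from 6 to 48 hpf hnf4a fell by 3.43 and mttp by 4.55 on the log2 scale of the edgeR fit, while apoba rose by 6.68, apobb.1 by 5.34 and apoa2 by 8.53. A few genes taking most of the counts was argued against, as hnf4a changed by -3.24 under library totals, the highest of 3 scalings. Dilution by RNA of other cells alone would leave yolk RNA at most 10.6% of the counts at 48 hpf for hnf4a and 4.85% for mttp, or 14.3 and 6.47% with either gene 2 SE higher. The 1862 genes outside the focal list that were at least 8-fold higher in yolk at 6 hpf held 9.85 to 10.7%, which argued against dilution as the whole cause for mttp, if these transcripts are of the yolk itself. For hnf4a it cannot be told apart from a change within the yolk, as that share does not pass its limit. Changes outside the yolk stay open.

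Proliferation genes were higher in yolk than in whole embryos at 48 hpf under TMM, but 0 of 20 were higher under library totals. That difference therefore depended on the scaling. The difference between tissues in the step from 26 to 48 hpf was another matter, as 19 of 20 genes or more passed under each of 3 scalings. For this part the abundance of a few genes was argued against. A change in the share of dividing cells in either tissue may underlie it, and was not tested.

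Values of other libraries apart from their group follow, with marker sums and focal genes tested in yolk only. Whole-embryo replicate 2 at 6 hpf had a total of 38507223 counts (others 35606043 to 35862670) and 8.284% of them in the 10 most abundant genes (others 6.919 to 7.131). That share was 10.29% in whole-embryo replicate 1 at 48 hpf (others 9.029 to 9.15). The TMM factor of whole-embryo replicate 4 at 26 hpf was 1.507 (others 1.463 to 1.468). In yolk at 6 hpf lens markers summed to 157.9 CPM in replicate 4 (others 16.39 to 31.01), and mttp was at 9580 CPM in replicate 1 (others 8530 to 8670). In yolk at 10 hpf gastrula genes summed to 1061 CPM in replicate 4 (others 790 to 820.7), and hnf4a was at 324 CPM in replicate 2 (others 413 to 431). At 48 hpf yolk replicate 1 had hnf4b at 135 CPM (others 91.6 to 96.7) and apoa1b at 53800 CPM (others 36500 to 39000). Replicate 2 had apoba at 9960 CPM (others 11200 to 11400), and replicate 3 had apoeb at 9030 CPM (others 9560 to 9660).

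Tissues differed in their change from early to late ages for 7417 and 6040 genes and for 8 lists by camera adjusted p. They were apolipoproteins and focal genes at 6e-04 each, plasma proteins at 0.0011, proliferation at 2.4e-11, muscle at 6.7e-05, pigment at 0.00018, lens at 0.00022 and ribosomal proteins at 2.1e-07. The step from 26 to 48 hpf differed for 2439 and 3474 genes and for 9 lists. Camera adjusted p was 0.039 for cholesterol synthesis, 2.9e-05 for the lysosome, 1.9e-16 for proliferation, 0.0044 for epidermis, 2.3e-05 for erythroid, 0.00099 for macrophage, 0.04 for endothelial, 0.00097 for lens and 5e-08 for ribosomal genes. With an estimated correlation 0 of these 8 and 0 of these 9 list calls held.

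Chance was excluded for the number of genes called in each contrast of 2 groups, as 1 of 35 splits of its own libraries, the real one, gave as many. For yolk against whole embryo the real counts were 11205, 13481, 9764 and 15642 by age, for the yolk steps 10415, 10946 and 5532, and for the whole-embryo steps 10754, 15999 and 12214, when the highest other split gave 2. Among the 8 splits that part all same-numbered pairs in the 5 paired contrasts the real one was again highest, and the others gave 0. So few splits cannot exclude chance in those contrasts. For the change from early to late ages it was 1 of 40 drawn splits (13457 genes, highest other 3287). For the step from 26 to 48 hpf it was 2 of 100, with 7589 genes against 9478 and 7298 in other splits. Splits can hold the tissue difference, as the highest did by exchanging both tissues at 48 hpf, so the test cannot exclude chance here. For genes called at all 4 ages it was 1 of 100 in either direction, with 1792 higher and 818 lower against 0, again from splits that mix the groups.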

How the results depend on the processing

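The tests with a replicate block on the contrast's libraries alone, and without COX3, were chosen after the data were seen, and the other alternatives before the data were examined. Of 26 counts of genes all stayed within 1.5 times their value under DESeq2 size factors, the DESeq2 Wald test, no low-count filter, removal of mitochondrially encoded genes and a replicate block on all libraries. Library totals moved 13 of them. They gave 3931 higher and 12344 lower in yolk at 10 hpf, 2633 and 14969 at 26 hpf and 3029 and 11166 at 48 hpf. They also gave 5986 rising and 2626 falling for yolk from 26 to 48 hpf, 2865 falling for whole embryos from 6 to 10 hpf, and 4500 and 1992 for the difference in the last step. Genes called at all 4 ages became 953 and 3594. Leaving out the composition factor also moved the median of all genes, by 0.37 for yolk from 26 to 48 hpf, 0.36 for whole embryos from 6 to 10 hpf and 0.45 for the difference in the last step. With the contrast's libraries alone 4109 genes were lower in yolk at 26 hpf, 6411 rose and 5803 fell in whole embryos from 26 to 48 hpf, and 818 were lower at all ages. A replicate block added to such a fit gave 4420 lower at 26 hpf, 5378 rising in yolk from 10 to 26 hpf, 1830 rising and 1852 falling in yolk from 26 to 48 hpf, and 6458 and 5948 in whole embryos. In that fit of yolk from 26 to 48 hpf, whose replicate numbers do not pair the libraries, adjusted p was 0.058 for hnf4a, 0.058 for mttp and 0.053 for apoeb. The cause was not tested. Leaving out 1 library moved no count by more than 1.5 times.

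Of 827 pairs of a named gene and a comparison, the direction reversed under 1 alternative other than leaving out a library, where pcna at 48 hpf went to -0.02 under library totals. Of the 776 pairs that passed, calls ended for 35 under library totals, 13 with no low-count filter, 11 with DESeq2 size factors, 9 by the DESeq2 Wald test and 4 with the replicate block on all libraries. With the contrast's libraries alone 19 ended, and 37 with a replicate block added. Leaving out 1 library ended calls in 281 of 8672 fits of a pair. The block on all libraries ended 1 of 175 list calls, that of macrophage markers in whole embryos from 6 to 10 hpf at adjusted p = 0.05. An estimated correlation ended 148 list calls. In simulation with few changed genes, 2-fold changes were recovered less often than 4-fold ones.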

Other observations

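The test below was chosen before its result was seen, and the heart genes were chosen after their values were seen. At 26 hpf the mean levels of 6 heart muscle genes were higher in yolk than in whole embryos, in CPM without TMM scaling, over n = 4 libraries. Ventricular myh7 was at 95.5 ± 25.4 against 53.9 ± 4.99 CPM, and myl7, a myosin light chain of the heart, was at 49.9 ± 19.3 against 22.1 ± 3.77. As percent of the whole-embryo level yolk held 177 of myh7, 226 of myl7, 232 of cmlc1, 201 of tnnt2a, 200 of atrial myh6 and 175 of nppa. Of the transcription factors tbx20 stood at 89.9%, and gata4 at 719%, near its 630% at 6 hpf. Compared within same-numbered pairs, the muscle genes were higher in yolk in 4 of 4 pairs, except nppa with 3. Unpaired, the lowest yolk library held 60.2 CPM of myh7 against at most 59.3 in whole embryos, and for cmlc1 both were at 14.4, while myl7, myh6 and tnnt2a overlapped. Replicate 4 was the lowest yolk library for each, with nppa at 2.37 CPM under all whole embryos (3.48 to 5.3). Summed muscle markers, mostly of skeletal muscle, stood at 31.1% of the whole-embryo level in yolk replicate 1 and at 0.205 to 0.552% in the others. By 48 hpf yolk held 5.24% of the whole-embryo level of myh7, 5.24% of myl7, 4.29% of cmlc1, 4.75% of tnnt2a and 0.542% of nppa. Atrial myh6 stayed at 154%, with 18.7 ± 5.66 against 12.1 ± 1.73 CPM, and tbx20 was at 41.3%.

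Sums over a marker list can rest on 1 abundant gene. Macrophage and leukocyte markers in yolk stood at 471, 712, 1280 and 205% of the whole-embryo level by age, and the protease gene ctss2.1 made up 91.2, 83.6, 86.5 and 4.43% of that yolk sum. Yolk held this gene at 5570 ± 468 CPM, without TMM scaling, as early as 6 hpf.

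Whole embryos include the yolk, so yolk RNA may make up a constant share of their RNA at each age. Genes found mainly in yolk would then all have the same ratio of whole-embryo to yolk level. The median ratio was 12.8% over 20 genes at 6 hpf, 12.2% over 36 at 10 hpf, 9.91% over 41 at 26 hpf and 6.89% over 45 at 48 hpf. The upper over the lower quartile was 1.48, 1.71, 1.88 and at most 2.83 by age, which leaves the share undecided. Body transcription of these genes could widen the spread, and their choice, which differed by age, narrow it. At 6 hpf hnf4a, mttp and pla2g12b stood at 10.8% each, dgat2 at 10.7%, apoba at 11.4% and apobb.1 at 12.4%. Higher were apoa1a at 17.5%, apoeb at 31.5% and, not a gene found mainly in yolk, apoc1 at 228%.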
